A study of Homo sapiens with 6 samples.

How the data were processed

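Messenger RNA levels were measured in NCM-460 cells, an epithelial line derived from normal human colon, with a NanoString nCounter assay, in which barcoded probe pairs are hybridised to RNA and counted one by one without amplification or labelling. Per the labels' protocols, total RNA was extracted with Trizol, brought to 33 ng per microlitre and prepared by a core facility following the manufacturer's instructions. The 6 samples form 2 groups of 3: cells transfected with a control siRNA and cells transfected with pri-miR-135b, the primary transcript of the microRNA miR-135b. The series' design text speaks of scrambled and miR-135b oligos and the sample labels of control siRNA and pri-miR-135b; the groups are named here as in the sample labels. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

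The authors deposited raw counts, whole numbers per probe, for 6 positive spike probes, 8 negative control probes and 236 genes. The counter, its software and any lane correction are not given in the sources used here. The authors also deposited a table of normalized counts, used here as signal values on a linear scale. Set against the raw counts, all 1416 of its values equalled the raw count times 1 factor per sample within 0.02, with the single raw count of 0 set to 1 before scaling. What the factors (0.826 to 1.29) were computed from is not given in the sources used here. The spike probes are absent from that table. In the raw file the usual reference genes (CLTC, GAPDH, GUSB, HPRT1, PGK1 and TUBB) carry the same class as the other genes.

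Gene symbols are those of the files. Of the 236 genes, 234 matched a RefSeq transcript accession without its version in a gene table of assembly GRCh38.p14 and 2 matched by symbol or synonym only. The current symbol differs for 6 of them, among them IL8 (now CXCL8), CTGF (now CCN2), MLL (now KMT2A) and CDC2 (now CDK1). The files give no coordinates, and no genome was used.

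Total counts over the 236 genes ranged from 250792 to 392207 per sample, and replicate 3 had the lowest total in both groups. Background was set per sample as the mean of its 8 negative control probes plus 2 SD, which came to between 14.7 and 26.1 counts. A gene was tested if its raw count exceeded that level in at least 3 of the 6 samples. This left 174 genes, and 47 of the 62 untested genes were above background in no sample. Spike and control probes stayed out of library sizes and tests. The counts were tested with edgeR 4.0.16 (TMM normalization, glmQLFit and glmQLFTest with default settings, group as the only term) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 174 genes and a threshold of 0.05. All adjusted p-values of single genes below come from this test unless another is named. Fold changes are miR-135b over control. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. The test draws each gene's variance toward a trend over all genes. The SE and p-value of a gene therefore rest on this pooled spread as well as its own. Group values are TMM-normalised counts, scaled to the mean effective library size, as mean ± SD with n = 3. Counts near background include non-specific counts, which pull a fold change toward 1.

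The procedure was tested on 50 simulated data sets of the 174 genes, with 20 genes changed by each of 3 folds. These used the means, library sizes and dispersion trend of this comparison. No gene was given a spread of its own beyond the trend, so the rates are best-case figures. It recovered 71.7% of genes changed by 1.2-fold, 90.8% of those changed by 1.5-fold and 97.1% of those changed by 2-fold, and 4.22% of its calls were false. Without any change it called 0.04 genes per data set on average.

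Before the data were examined, 22 gene lists were fixed from general knowledge, including lists of blood cell, fibroblast and endothelial markers. The 19 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and with an estimated one, and with fry. camera compares a list with the other tested genes. fry tests whether its genes move on balance one way, or with its mixed p in either direction, and makes no comparison with other genes.

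The genes named were chosen by a rule fixed beforehand: the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, every measured gene of the miR-135 target list, every reference gene, and up to 4 examples per list. CCND1, BIRC5, TYMS, CYP1A1, FGF1, BCL2, AKT1 and ATM were added after their values were seen. IGF1 is named only for its mean count, the highest among the tested markers of other cell types. Some genes that the rule selects are not reported here. The alternatives were DESeq2 1.42.0 size factors, scaling by reference genes, by positive spikes or by total count, the DESeq2 Wald test, limma-voom, limma on the deposited normalized values (pseudocount 1), background subtraction with a floor of 1, no filter and a stricter filter (above background in all samples and a mean count of at least 50), a robust fit, the replicate number as a block and leaving out each sample in turn. Background-subtracted counts were scaled by reference genes and tested with limma.

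Replicates of one group differed by more than counting noise: chi-square per degree of freedom over the 174 genes was between 1.79 and 5.25 for the 6 pairs, so no pair was treated as 1 sample deposited in duplicate. This does not tell repeat hybridisations of 1 RNA from separate cultures. The biological coefficient of variation estimated by edgeR was 3.7%. A test of miR-135b seed matches in 3' UTRs was planned and not made, because no transcript sequences were used here.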

Results

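The data describe 236 cancer-related transcripts in NCM-460 human colon epithelial cells, 3 samples given a control siRNA and 3 given pri-miR-135b. The comparison asks how raising miR-135b, a microRNA linked to colon cancer, changes these transcripts. Total gene counts were 333708, 392207 and 250792 in control replicates 1 to 3, and 391786, 325012 and 251413 in the miR-135b replicates. Between 159 and 183 genes per sample exceeded background. miR-135b itself is not among the 236 genes, so the transfection was not checked at the level of the microRNA.

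Between the 2 groups a large part of the measurable panel differed by small amounts and a few transcripts strongly. By the sample labels the groups also differed in the kind of RNA given, while the series' design text speaks of oligos for both. The differences therefore cannot be assigned to miR-135b alone. IL8, a neutrophil-attracting chemokine, rose 4.60-fold, CTGF, a secreted matrix-associated factor, rose 2.20-fold and the transcription factor ETS1 rose 2.15-fold. The anti-apoptotic gene BCL2L1, the CDK inhibitor CDKN1A and CTNNB1, which encodes beta-catenin, each rose by 1.58-fold to 1.61-fold. The largest falls were in the tyrosine kinase SYK and the TGF-beta receptor TGFBR2, both 1.64-fold lower, followed by E2F1, FGFR3 and DAPK1 at 1.54-fold, 1.53-fold and 1.52-fold lower. Of the 174 genes tested, 75 (43.1%) passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 31 higher and 44 lower. Only 6 of the rises and 5 of the falls reached 1.5-fold, and 31 of the 75 changes were under 1.2-fold. The 2 groups did not overlap in 90 of the 174 tested genes, where chance gives 10%. They did not overlap in 70 of the 75 called genes, which were selected for differing between the groups. The split between directions depended on scaling: 41.3% of calls were higher with TMM and 55.2% with reference genes, with 67 calls. Scaling by the positive spikes left 27 calls. Among the genes selected by the rule or added later, it alone ended the calls of 13, with adjusted p from 0.0624 (MYC) to 0.834 (PGK1). Their log2 fold changes kept their direction, at -0.395 for MYC against -0.437 with TMM, 0.366 against 0.322 for MET, 0.317 against 0.269 for MCL1, 0.327 against 0.284 for CDH1 and -0.074 against -0.116 for PGK1. CDC25B, IFNGR1, NF1, PPARG, TYMS, XRCC5 and YES1 were among the others. In the 6 fits that each left out 1 sample the number of calls ranged from 60 to 76, 52 of the 75 calls were kept in all of them, and none changed sign.

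**Figure D1:**
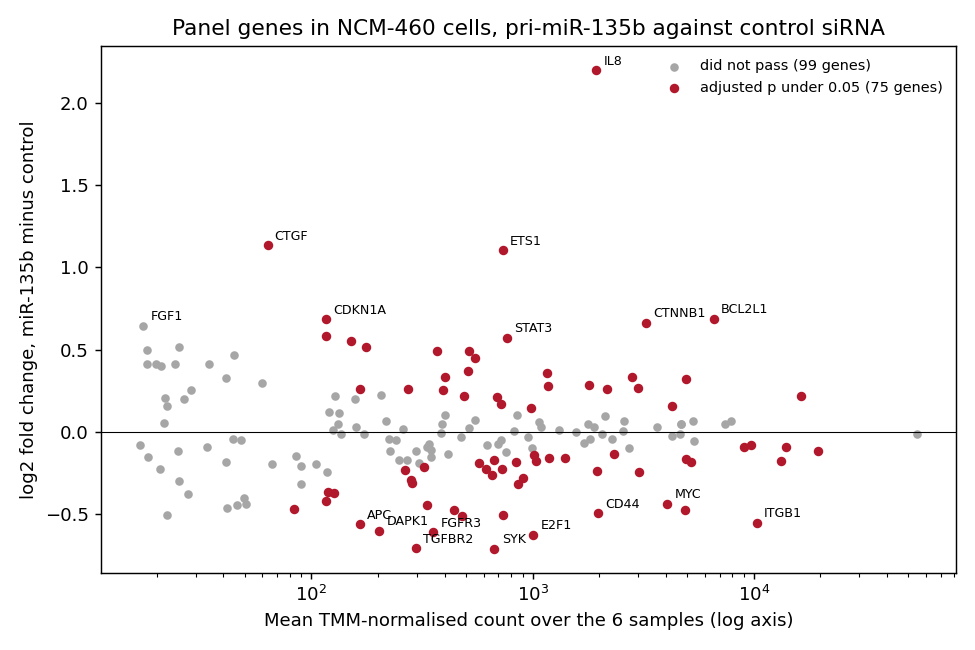
Each point is 1 of the 174 tested genes, with its mean TMM-normalised count over the 6 samples on a log axis and its log2 fold change, miR-135b minus control, on the vertical axis. The 75 genes past an adjusted p of 0.05 are red, and IL8 lies apart at 2.20.

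IL8 had 694.1 ± 16.7 normalised counts in control and 3183.3 ± 197 in miR-135b samples (SD, n = 3), a log2 fold change of 2.20 (SE 0.05, edgeR adjusted p = 9.4e-20). ETS1 went from 463.8 ± 23.2 to 998.1 ± 69.7 (log2 fold change 1.11, SE 0.06, edgeR adjusted p = 2.09e-12). BCL2L1 went from 5039 ± 45.5 to 8110.4 ± 192.7 (log2 fold change 0.69, SE 0.03, edgeR adjusted p = 5.5e-14). CTGF was a less abundant transcript, with 39.2 ± 4.58 against 87.4 ± 14.2 counts (log2 fold change 1.14, SE 0.18), and subtracting background raised its log2 fold change to 1.46. Smaller rises were found for the cytokine LIF (log2 fold change 0.58, SE 0.13), the transcription factor STAT3 (1.49-fold), the kinases FYN (1.47-fold) and PIM1 (1.43-fold), the cell cycle transcription factor E2F3 and the stress-response gene GADD45A (both 1.41-fold). Among the largest falls, ITGB1, the integrin beta-1 chain, was the most abundant, with 12272.4 ± 88.4 counts in control and 8365.3 ± 130.2 in miR-135b samples (log2 fold change -0.55, SE 0.03, edgeR adjusted p = 1.92e-13). SYK went from 833.9 ± 68.2 to 510 ± 12.9. The list of falls also held cyclin E1 (CCNE1, 1.43-fold lower), the receptor ERBB3 (1.42-fold), the hyaluronan receptor CD44 (1.41-fold), the calcium-binding protein S100A4 and the AP-1 factor FOSL2 (both 1.39-fold). Of these 24 largest rises and falls, 23 passed the threshold in every alternative fit that tested them. The exception was S100A4, whose control samples spread widely (5672.9 ± 1042.4) and whose adjusted p was 0.0977 in the robust fit.

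Genes described as direct targets of miR-135b or its sister miR-135a were examined first among the lists fixed beforehand. The sources of these descriptions were not traced, so some may rest on this same experiment. Of the 6 target genes on the panel, 4 fell: TGFBR2, DAPK1, a pro-apoptotic kinase, APC, the colon tumour suppressor that promotes beta-catenin degradation, and MYC. TGFBR2 went from 368.5 ± 11.2 to 225.1 ± 15.5 counts (log2 fold change -0.71, SE 0.08, edgeR adjusted p = 2.25e-07). DAPK1 went from 244.6 ± 26.6 to 160.4 ± 17.1 (-0.60, SE 0.11, edgeR adjusted p = 6.3e-05), APC from 197.4 ± 3.7 to 132.8 ± 12.5 (-0.56, SE 0.11, edgeR adjusted p = 0.000121) and MYC from 4663.9 ± 121.4 to 3443.8 ± 122 (-0.44, SE 0.04, edgeR adjusted p = 3.28e-09). The same number, 4, passed when adjusted over the list alone, and all 4 were kept in each fit that left out a sample. The other 2 did not pass. Of these, the estrogen receptor gene ESR1 lay close to background, at 20.2 ± 4.85 against 23.5 ± 4.55 counts, and its log2 fold change had a 95% interval of -0.31 to 0.72. The list's median log2 fold change was -0.50. It did not pass camera against the other genes of the panel after adjustment over 19 lists (p = 0.00612, adjusted p = 0.116, adjusted p = 0.888 with an estimated correlation), and passed fry (adjusted p = 0.00142). Over the alternatives the adjusted camera p ranged from 0.0387 to 0.194, and it passed with reference gene scaling (0.0387), spike scaling (0.0466) and no filter (0.0397), though with an estimated correlation in none of these.

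**Figure D2:**
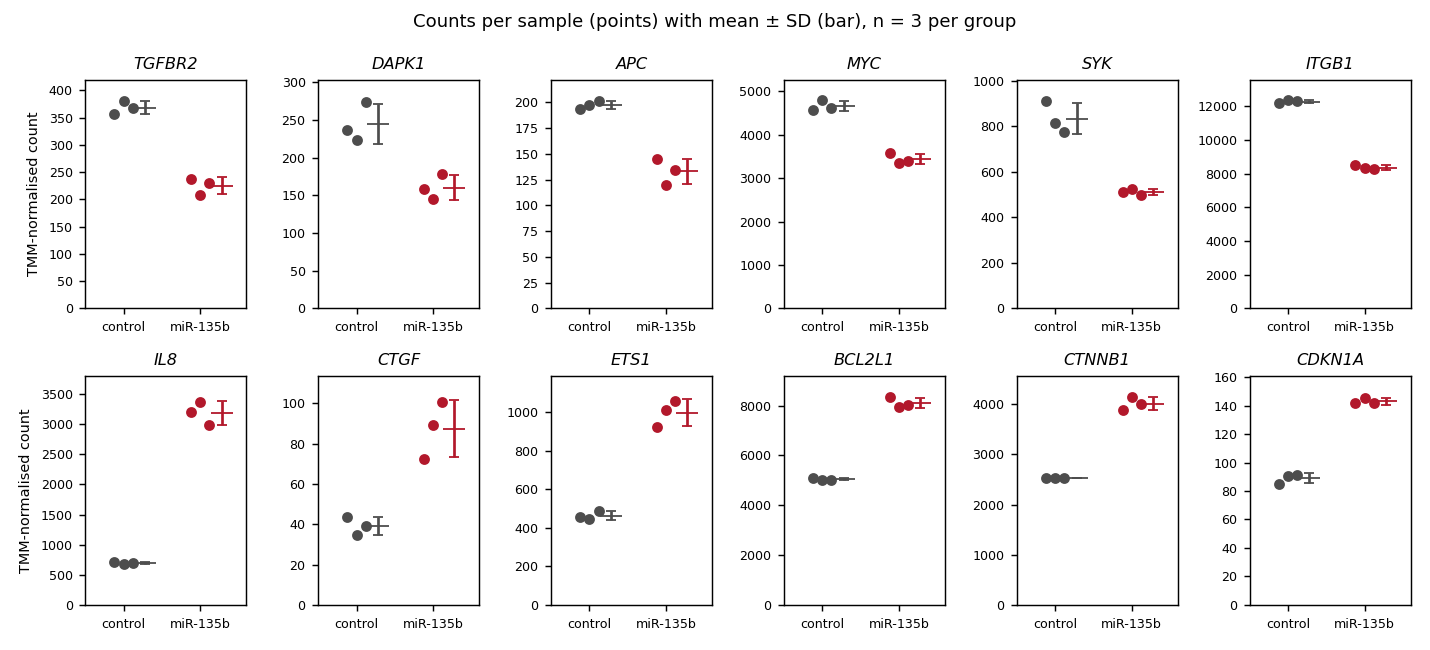
TMM-normalised counts of 12 genes, 1 point per sample with the group's mean ± SD beside it (n = 3), on linear axes that start at 0. In the upper row every miR-135b sample lies below every control sample, and in the lower row above.

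The Wnt list held CTNNB1 and APC together with transcripts known to respond to beta-catenin. Of 7 tested members, 3 rose and 3 fell (6 when adjusted over the list alone). CTNNB1 went from 2527.9 ± 7.78 to 4005.4 ± 129.9 counts (log2 fold change 0.66, SE 0.04, edgeR adjusted p = 2.09e-12), while APC, MYC and CD44 fell. The other rises were small, CCND1 at 1.10-fold and PLAUR at 1.12-fold. The CCND1 call was lost without control replicate 3 (adjusted p = 0.155), miR-135b replicate 1 (0.172) or miR-135b replicate 2 (0.0834), and the PLAUR call without control replicate 1 (0.151), miR-135b replicate 1 (0.131) or miR-135b replicate 2 (0.127), all by edgeR. Over all alternatives their adjusted p ranged from 0.0103 to 0.489 for CCND1 and from 0.00571 to 0.38 for PLAUR. Of 6 tested members of the TGF-beta list, TGFBR2 fell and TGFBI, a TGF-beta-induced matrix protein, rose 1.29-fold (2 when adjusted over the list alone). Neither list passed camera (adjusted p = 0.838 and 0.89). For the TGF-beta list camera gave the direction up, and the median, mean and fry the direction down.

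Among 20 tested cell cycle drivers, 2 rose and 6 fell, and 1 rise and 4 falls were kept in each fit that left out a sample. The falls were led by E2F1 (1222 ± 34.8 to 788.7 ± 37.3 counts) and CCNE1, which act at entry into S phase, with CDC25B and TYMS lower by 1.17-fold and 1.13-fold. E2F3 rose. Among 8 tested cell cycle inhibitors and stress-response genes 2 rose and 2 fell. CDKN1A (89 ± 3.71 to 142.8 ± 2.35 counts) and GADD45A rose, and the CDK inhibitor CDKN2C was called 1.29-fold lower. The CDKN2C call was lost without control replicate 1 (edgeR adjusted p = 0.0543) or 2 (0.0759) or without miR-135b replicate 2 (0.0568) or 3 (0.0524), and over all alternatives its adjusted p ranged from 0.00484 to 0.216. Both rises and neither fall were kept in each fit that left out a sample. Of 13 DNA repair genes 4 fell and none rose. XRCC5, which binds DNA ends, was 1.13-fold lower and the only 1 of the 4 kept in each fit that left out a sample. Adjusted over the list alone, 8 cell cycle drivers, 5 inhibitors and stress-response genes and 4 repair genes passed. None of these lists passed camera (adjusted p = 0.838 for each).

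Of 8 tested apoptosis regulators 3 rose and 1 fell, and 2 rises and the fall were kept in each fit that left out a sample. The survival genes BCL2L1 and MCL1 (log2 fold change 0.27, SE 0.04) rose, and DAPK1 fell. Of 5 tested NF-kB and inflammatory genes, IL8 and LIF rose. The other 3 did not pass, and 6 of the 11 members on the panel did not exceed background often enough to be tested. Of 5 tested interferon response genes, the receptor IFNGR1 rose 1.16-fold and the other 4 did not pass. Adjusted over the list alone, 4 apoptosis, 2 inflammatory and 1 interferon response genes passed. By camera the adjusted p of these 3 lists was 0.838, 0.838 and 0.877. For the interferon list camera and fry gave the direction up, and the median (-0.042) and mean (-0.085) were negative.

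Receptor tyrosine kinases moved both ways. Of 10 tested, FGFR3 and ERBB3 fell, MET, the hepatocyte growth factor receptor, rose 1.25-fold, and ERBB2 was called 1.14-fold lower. The ERBB2 call was lost without control replicate 1 (edgeR adjusted p = 0.0537) or 3 (0.128), without miR-135b replicate 1 (0.111) or 2 (0.0568). It was kept in 8 of 18 alternatives, with an adjusted p between 0.00771 and 0.656. Of 11 MAPK and PI3K signalling genes 1 rose and 4 fell, and 2 of the falls, NF1 (1.21-fold lower) among them, were kept in each fit that left out a sample. SYK fell and FYN, PIM1 and YES1 (1.11-fold) rose among 8 cytoplasmic kinases. Of 10 AP-1, ETS and immediate early genes 2 rose (ETS1, and JUN at 1.37-fold) and 4 fell, led by FOSL2 and MYC. All 6 tested adhesion and cytoskeletal genes changed: 3 rose, among them CTNNB1 and E-cadherin, CDH1 (1.22-fold), and ITGB1, CD44 and S100A4 fell. Adjusted over the list alone, 4 receptors, 8 MAPK and PI3K signalling genes, 5 cytoplasmic kinases, 6 AP-1 and ETS genes and 6 adhesion genes passed. None of these lists passed camera (lowest adjusted p = 0.838). The median and mean of the adhesion list were negative while camera and fry gave the direction up, and for the cytoplasmic kinases fry alone gave the direction down. By limma, over all 19 lists, camera called 0, with 1 list at an unadjusted p under 0.05. fry called 9 lists for a shift in one direction and 18 for change in either direction. The 18 included the list of reference genes (fry mixed adjusted p = 0.0345).

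The reference genes and markers of other cell types were counted as well. GAPDH had 54657.3 ± 377.8 counts in control and 54258.6 ± 428.4 in miR-135b samples. Of the 6 reference genes only PGK1 passed (log2 fold change -0.12, SE 0.03, edgeR adjusted p = 0.000973). The others had log2 fold changes between -0.10 (CLTC) and 0.05 (TUBB), TUBB passed with the stricter filter alone (0.08, adjusted p = 0.0481), and the sign for GAPDH, GUSB and HPRT1 turned under other scalings. Of 14 blood cell markers on the panel 2 (CD34 and TAL1) could be tested, and of 9 fibroblast and endothelial markers 4 could. None of these passed, and the highest mean among the tested ones was 25.3 counts, for IGF1 in control. Of 5 tested epithelial markers 1 rose (CDH1) and 3 fell, of which ERBB3 alone was kept in each fit that left out a sample (camera adjusted p = 0.838). Adjusted over the list alone, 4 epithelial markers and 1 reference gene passed.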

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

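Over 18 alternatives the number of called genes ranged from 27 to 80, and stayed within 1.5 times of 75 in 17 of them. Scaling by positive spikes gave 27 calls, 14 higher and 13 lower. Background subtraction, with limma and reference gene scaling, gave 28 lower, and reference gene scaling without subtraction 30. Spike counts were between 8.18% and 11.3% of gene counts. The median log2 fold change of all genes moved only between -0.04 and 0.03, and the share of higher calls between 40% and 56.9%. The 56.9% came from the background-subtracted counts, and reference gene scaling without subtraction already gave 55.2%. The count of lists past camera was 0, and became 1 with reference gene scaling (miR-135 targets, adjusted p = 0.0387), 1 without a filter (the same list, 0.0397) and 2 with spike scaling (the same list, 0.0466, and NF-kB and inflammatory genes, 0.0334), none with an estimated correlation; the cause was not tested. Leaving out 1 sample gave 60 to 76 calls. Over all tested genes, each weighted alike whatever its count, same-numbered samples did not deviate together (correlations 0.02, -0.13 and 0.13). The main fit did not take the numbers as pairs, but a shared replicate effect is not excluded. S100A4 kept the same replicate order: 5630.7, 4652.2 and 6735.8 normalised counts in control and 4275.7, 3504.1 and 4408.8 in miR-135b samples. How many genes share an order was not counted. With the replicate block 80 genes passed, including all 75, and not every sample correlated best with its own number. Of 1197 values of genes that the rule selects or that were added, 1094 kept direction and call, 85 lost the call, 4 gained it and 14 turned sign, all 14 in genes that passed in neither fit. GAPDH (-0.01) became 0.016 with DESeq2 size factors and with the Wald test, 0.033 with reference genes, 0.034 with spikes, 0.001 with total counts, 0.032 with background subtracted and 0.027 with the stricter filter. GUSB became 0.012 with reference genes and with spikes, 0.014 with background subtracted and 0.006 with the stricter filter, and HPRT1 0.005 with spikes. Leaving out 1 sample moved HIF1A, a hypoxia factor, between -0.029 and 0.109. The 62 genes too close to background were not tested, and 47 of them were above it in no sample; how far depth limits these was not tested. The planned seed-site comparison was not run, as no transcript sequences were used.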

Other observations

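The tests of explanations in this part were chosen after the results they bear on were seen, except the counts of other splits.

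Other groups of the panel added a few changes. Of 6 nuclear receptor genes and partners, PPARG, a lipid-sensing receptor, fell 1.25-fold and the other 5 did not pass. Of 7 tested growth factors LIF rose, PDGFA and AREG were called lower (log2 fold changes -0.47 and -0.18) and 4 did not pass; adjusted over the list alone, 3 growth factors and 1 nuclear receptor passed. The PDGFA call was lost without miR-135b replicate 1 (edgeR adjusted p = 0.0531) and the AREG call without control replicate 3 (0.123) or miR-135b replicate 1 (0.101). Over the alternatives the adjusted p ranged from 0.00346 to 0.116 for PDGFA and from 0.00497 to 0.686 for AREG. Of 5 tested genes on the list of matrix proteases and inhibitors PLAUR alone was called, and 0 passed when adjusted over the list alone. By camera these 3 lists had an adjusted p of 0.838. Neither of the 2 tested hypoxia and angiogenesis genes passed, HIF1A (0.03, SE 0.06) and KDR (0.50, SE 0.29). CYP1A1, a detoxifying enzyme gene, had 48.7, 38 and 91.4 normalised counts in control replicates 1 to 3 and 37.4, 39.6 and 48.4 in the miR-135b samples (log2 fold change -0.44, SE 0.25). It did not pass (edgeR adjusted p = 0.162), but did without control replicate 2 (0.011) or miR-135b replicate 3 (0.0414), and without control replicate 3, the sample at 91.4, its log2 fold change was -0.054 (adjusted p = 0.826), against -0.711 at the other end of its range. FGF1, KDR, MMP2 and BCL2 exceeded background in all 3 miR-135b samples and in no control sample, where background was set at 15.5, 26.1 and 19.7 counts in the controls and at 16, 16.7 and 14.7 in the miR-135b samples. Their normalised counts overlapped between the groups, and log2 fold changes of 0.40 to 0.65 did not pass (edgeR adjusted p from 0.103 to 0.279). Leaving out 1 sample lowered these to 0.42 for FGF1, 0.28 for MMP2 and 0.12 for BCL2 (each without control replicate 1) and to 0.26 for KDR (without miR-135b replicate 3). FGF1 passed without control replicate 3 (0.0397), with an adjusted p of up to 0.356 over the alternatives, and with background subtracted the log2 fold changes were 2.26 for FGF1, 1.61 for BCL2, 1.28 for KDR and 0.93 for MMP2, none past the threshold. AKT1 and ATM, kinase genes that most cells use, stayed under background in all 6 samples, at 4 to 13 and 2 to 8 raw counts. Whether their probes respond poorly or the transcripts are scarce was not tested.

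The comparison was refitted for all 10 splits of the 6 samples 3 against 3. The real split called 75 genes and the highest of the others 0, so 1 of the 10 splits gave as many. Every other split put samples of both groups on each side, so the difference between the groups added to the spread there. Their 0 calls are therefore not the number that chance alone would give. For lists by camera the real split gave 0 and the highest other 1, so all 10 gave as many. With 10 splits no share under 0.05 can be reached.

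The fall of 4 of the 6 measured miR-135 targets, APC and TGFBR2 among them, was set against the scaling. In every setting the log2 fold changes of these 4 stayed at -0.394 or lower, while no setting shifted the median of all tested genes by more than 0.063. The choice among the scalings tried therefore does not account for the fall. These scalings lie close together, so a larger error shared by all of them was not tested. Spike scaling ended the MYC call (edgeR adjusted p = 0.0624). The fall of these 4 may reflect direct repression by the transfected microRNA, but sites in the transcripts were not examined. Other genes that fell as far (SYK, E2F1, FGFR3 and ITGB1) were not on the list. If the groups received different kinds of RNA, as the sample labels say, a reaction to this cannot be told apart from such repression.

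The rise of IL8 was the strongest change. It stayed at a log2 fold change of 2.157 or more in every setting, which argues against the scalings tried or a single sample as the cause. By the sample labels the groups received different kinds of RNA, a siRNA and a primary microRNA transcript. A reaction to this difference stays open, because 0 groups received an unrelated pri-miRNA. An effect of miR-135b itself, with STAT3, LIF, JUN and ETS1 rising beside IL8, stays open too and was not tested.

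CTNNB1 rose and APC fell, so a candidate explanation for part of the other changes is a general rise of beta-catenin target transcripts. The values leave it open: of the 5 measured targets on the Wnt list, 2 fell (MYC by 0.44 and CD44 by 0.50 on the log2 scale), 2 rose (CCND1 by 0.14 and PLAUR by 0.17, calls lost without some samples, with log2 fold changes of at least 0.098 and 0.126 in every setting) and BIRC5 did not pass (-0.07, SE 0.04). MYC is itself on the list of miR-135 targets, so its fall may have another origin, which leaves 1 fall, in CD44. Panel genes outside the Wnt list that may respond to beta-catenin were not weighed. Protein levels and the activity of beta-catenin were not measured here.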
